A study of Mus musculus with 16 samples.

How the data were processed

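RNA was measured in macrophages and monocytes sorted from subcutaneous MN/MCA1 sarcomas of C3 wild-type and C3 knockout mice, 21 days after the tumour cells were injected. MN/MCA1 is a transplantable mouse fibrosarcoma line. Libraries came from 5 ng of RNA each by the SMART-Seq v4 kit, which copies full-length transcripts and does not mark strand, so reads of overlapping and antisense genes cannot be told apart. The 16 libraries fell into 4 groups of 4 by the titles, which also number the mice. The same animals gave both cell types, so the numbers pair macrophage and monocyte libraries. Correlations of the deviations from the group means between both libraries of a mouse were 0.417, 0.107, 0.031 and 0.207 in wild type and 0.052, 0.084, 0.211 and 0.083 in knockout. Between different mice they ran from -0.323 to 0.188 in wild type and from -0.227 to 0.136 in knockout, so the ranges overlap. No library of a group was a copy of another: the chi-square per gene between pairs ran from 10.1 to 47.8. The Spearman correlations of these pairs ran from 0.9874 to 0.9952.

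Per the submitters' processing notes, bcl2fastq 2.19.0.316, STAR 2.7.2b, DESeq2 and the mouse build GRCm38 were used. Their roles, the DESeq2 version and the annotation are not given in the sources used here. The authors deposited a matrix of log2 values for 30819 genes in the 16 libraries. No header names the transform. The values followed a regularized logarithm with 1 size factor per library, which draws low values together. The authors also deposited, per the file headers, a table of wild type against knockout for each cell type. Its base mean is a signal, the mean over all 16 libraries of reads divided by size factors, as deposited by the authors. Its log2 fold changes and standard errors are the authors' own, turned here to knockout minus wild type. Its Wald statistic is a score from the authors' fit. Its p-value and adjusted p-value columns are as the authors deposited them, with adjusted values for 14087 genes. The matrix had 0 columns of samples from elsewhere.

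Reads were recovered by inverting the transform with the authors' base mean. Of the values of 20443 genes with a base mean of at least 1, 81.5% lay within 0.05 of a whole read. The share was 97.3% at base means of 1 to 10, 97.4% at 10 to 100, 81.4% at 100 to 1000 and 41.5% above 1000, where the median distance from a whole read was 0.00251% of the value and the largest 0.197%. The mean of the rounded reads was within 1% of the deposited base mean for 99.7% of these genes. On simulated reads of 4000 genes, 100% of values were recovered. These were made with the same equation and size factors, so this checks the inversion and not whether the deposited values follow that equation. Recovered reads ran from 18689333 to 29049252 per library, with 17850 to 19654 genes detected and 8.31% to 12.95% of reads in the top 10 genes. Normalized reads are recovered reads divided by the size factor. Differences in log2 reads were 1.41 times those on the deposited scale in the comparisons of genotypes.

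The design, fixed before the data were examined together with the gene lists, the rule for named genes and the first set of alternatives, assumed counts or values to be put on the log2(value + 1) scale. The files held log2 values, so limma was fitted to them directly, with a trend and robust estimation. Genes were kept where the linear value reached 10 in at least 4 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each comparison used its own 8 libraries, and the difference of knockout effects between cell types used all 16. Exact permutation of 4 against 4 libraries cannot go below p = 0.0286 (two-sided), so adjusted p-values rest on limma's spread shared across genes. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. For each list that passed, the estimated correlation gave the highest adjusted p over its alternatives. The macrophage, monocyte, wild-type, knockout and difference tests called 15, 9, 14, 15 and 9 lists with the preset correlation, and 0, 0, 0, 1 and 0 with the estimated correlation. With the estimated correlation even the classical monocyte list did not pass between the cell types of wild-type mice (median -3.11, camera adjusted p = 0.0625). A list call lost with that setting therefore does not show that the list was unchanged. Fry called 7, 1, 22, 24 and 0. Median, mean and test differed in sign only in lists that did not pass camera, of which 2 passed fry.

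Genes were named by a fixed rule: C3, C3ar1, C5ar1, Itgam and Itgax, then the 10 largest rises and falls (5 each for the difference of effects) among called genes. These had to have a mean linear value of at least 50 in the higher group, in place of a minimum fixed for counts, no overlap between groups and a symbol that is not a predicted gene, pseudogene or mitochondrial gene. For each list described, the 2 to 4 members with the smallest p were added. Some genes that this rule takes are not reported here. Positions and symbols came from GENCODE M21 (GRCm38), which held 30758 of the gene IDs. Among the IDs 58 shared a symbol. Called genes were counted in windows of 5 Mb with 1000 shuffles of gene positions.

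The gene test was tested on simulated reads with known changes of 1.5, 2 and 4 fold, planted in genes with a mean of at least 50 normalized reads. Each gene was drawn independently, so recovery in weaker genes, or with variation shared between genes, was not measured. The test recovered 74.6%, 91% and 97% of the changes in the macrophage comparison and 55.2%, 77.6% and 98.5% in the monocyte comparison. It recovered 64.2%, 86.6% and 97% between cell types in wild type, 64.2%, 91% and 100% in knockout, and 50.7%, 79.1% and 93.9% for the difference of effects. Among unchanged genes it called 3, 4, 11, 11 and 4. The alternatives fixed in advance were no filter, no robust estimation, TMM scaling, voom with quality weights on the recovered reads, pseudocounts of 0.1 and 5, all libraries in 1 fit, the mouse as a block, each library left out and the estimated correlation. Added after the data were seen were a pseudocount of 1, voom without quality weights, array weights, the fit without genes of enriched windows, protein-coding genes only and the authors' deposited tables. The planned count models were not run, because the files hold no counts and only 81.5% of recovered values were whole at base means of at least 1. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.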

Results

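The series asked how the loss of complement component C3, the protein on which the complement cascades converge, changes the transcriptomes of macrophages and monocytes inside a tumour. MN/MCA1 sarcoma cells were injected under the skin of C3 wild-type and C3 knockout mice, and tumours were taken after 21 days. Both sorted populations carried CD45 and CD11b and lacked Ly6G and CD11c. Monocytes were positive for Ly6C and negative for F4/80, and macrophages were the reverse. The 16 libraries fell into 4 groups of 4 mice each, with both cell types taken from each mouse (mice 1 to 4 wild type, mice 6 to 9 knockout). Libraries were made from 5 ng of RNA. The reads recovered from the deposited values ran from 18689333 to 29049252 per library. Differences are given on the deposited regularized log2 scale or as fold changes of mean normalized reads. The deposited scale is compressed: between genotypes, differences in log2 reads were 1.41 times as large, so its values understate fold changes in reads.

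The targeted gene was measured first. C3 (GRCm38 chromosome 17, 57203970 to 57228136) fell from 4008 ± 858 to 1234 ± 168 normalized reads in macrophages (SD, n = 4 per group), a log2 difference of -1.13 ± 0.11 (SE; limma, adjusted p = 0.000215). In monocytes C3 fell from 15160 ± 718 to 4925 ± 288 normalized reads (SD, n = 4 per group), a log2 difference of -1.22 ± 0.05 (SE; adjusted p = 8.81e-08). The values of the knockout libraries did not overlap those of the wild-type libraries in either cell type, which goes with the labels. Reads assigned to C3 remained in all knockout libraries, at 30.8% of the wild-type mean in macrophages and 32.5% in monocytes. Values per gene do not show which exons these reads came from. Among the receptor genes, C3ar1 (log2 difference -0.12 in macrophages and -0.07 in monocytes) and C5ar1 (-0.15 and -0.12) did not pass the test in either cell type. Itgam, which encodes CD11b, fell in macrophages (-0.27, adjusted p = 0.0133) and in monocytes (-0.46, adjusted p = 0.0195). The macrophage call of Itgam was lost with all 16 libraries in 1 fit (adjusted p = 0.0728; range over all alternatives 0.00931 to 0.0728). The monocyte call of Itgam was lost without wild-type replicate 4 (adjusted p = 0.0578) or knockout replicate 8 (adjusted p = 0.0538), in a range of 1.13e-05 to 0.0578. Itgax, which encodes CD11c, fell in monocytes (-0.53, adjusted p = 0.0386). That call was lost without wild-type replicates 2, 3 or 4 (adjusted p = 0.105, 0.111 and 0.102) or knockout replicates 8 or 9 (0.0716 and 0.124), without the filter on low values (0.0516) and with TMM scaling (0.05), in a range of 9.65e-05 to 0.124. In macrophages Itgax did not pass (-0.23, adjusted p = 0.0795), but passed without wild-type replicate 4 (0.0462) and with TMM scaling (0.0492), in a range of 0.0462 to 0.295.

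**Figure D1:**
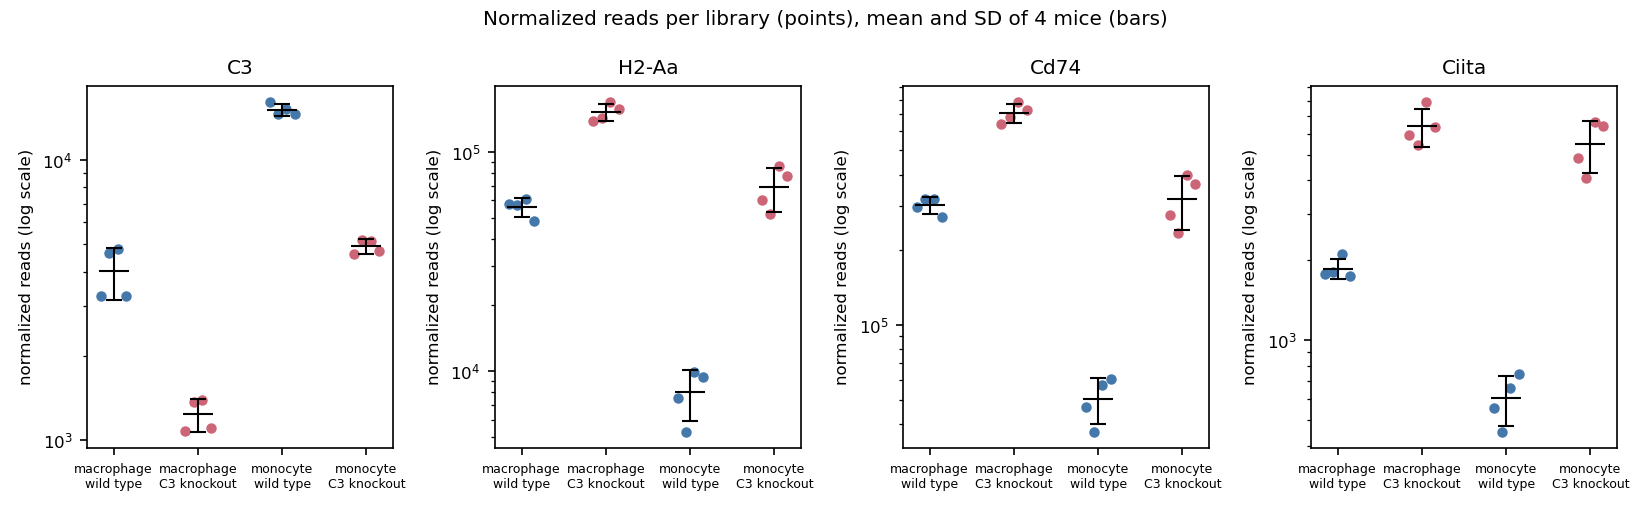
Normalized reads on a log axis for C3, H2-Aa, Cd74 and Ciita in each of the 16 libraries (points), with the mean and SD of the 4 mice of each group (bars). C3 was lower in the knockout libraries of both cell types, and H2-Aa, Cd74 and Ciita were higher.

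The first comparison asked which genes differ between knockout and wild-type macrophages. Of 13 antigen presentation genes of MHC class II 10 rose in knockout macrophages, but 3 fell adjusted over the list alone, and the list call was lost with an estimated correlation (adjusted p = 0.432). H2-DMb1, part of the peptide-loading machinery, rose 2.45-fold. Of the class II chain genes, H2-Aa rose by 1.08 on the deposited log2 scale (55840 to 150800 normalized reads) and H2-Eb1 rose 2.92-fold. Cxcl13, a B cell chemoattractant, was nearly absent from wild-type macrophages (5.82 ± 4.42 normalized reads) and reached 1848 ± 488 in knockout macrophages (SD, n = 4 per group; log2 difference 5.90 ± 0.22 SE, adjusted p = 1.42e-07). Of the genes of the type I interferon response 12 of 35 fell, of the lysosome 10 of 30 and of macrophage identity 7 of 18, but these list calls were lost with an estimated correlation (adjusted p = 0.436, 0.432 and 0.436). Vcam1, an adhesion molecule, fell to 0.238 of the wild-type mean. In all, 717 of 12568 genes tested passed (limma, adjusted p under 0.05), 323 higher and 394 lower in the knockout, and 214 of them differed at least 2-fold in reads. With TMM scaling 257 were higher and 420 lower. The values of both genotypes did not overlap in 13.1% of tested genes, against 2.86% by chance. The count was 458 without wild-type replicate 2.

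The 10 largest rises among non-overlapping genes with a symbol were those of Cxcl13, Mb21d2, Hebp1, Plekha7, Neurl1a, Trim34b, Kit, Timmdc1, Gdpd3 and Atp10d. Hebp1, a heme-binding protein gene (chromosome 6, 135137522 to 135198022), rose from 111 ± 21.8 to 2401 ± 162 normalized reads (SD, n = 4 per group). Kit, the receptor of stem cell factor, rose 7.14-fold and Mb21d2 22.5-fold. The 10 largest falls were those of Trim12a, Smarcd1, Trim5, Zfp125, Sema4b, Lpin1, Hdac9, Vcam1, Hbb-bt and Spats2. Trim12a (chromosome 7, 104299894 to 104315466) fell from 480 ± 54.5 to 1.99 ± 1.54 normalized reads (SD, n = 4 per group; log2 difference -4.14 ± 0.11 SE, adjusted p = 1.67e-09). Smarcd1, a chromatin remodelling subunit gene on chromosome 15, fell to 0.0657 of the wild-type mean. Lpin1, a phosphatidate phosphatase gene on chromosome 12, fell to 0.101 of it. Trim12a, Trim5 and Trim34b are neighbours from a family of similar sequences, so reads can be split between members, and their values are uncertain.

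Among the gene lists, 10 of 13 measured MHC class II presentation genes rose in macrophages and none fell (median log2 difference 0.96; camera with the preset correlation, adjusted p = 7.84e-13). The list call was lost at adjusted p = 0.432 with an estimated correlation, while the list passed fry (adjusted p = 0.000421). Adjusted over the list alone, 10 genes rose and 3 fell. Cd74, the invariant chain (2.34-fold), and Ciita, the master regulator of class II transcription (3.45-fold), were chosen after their values were seen. The type I interferon-stimulated list went the other way, with 12 of 35 genes lower (median -0.23, adjusted p = 5.80e-12; adjusted p = 0.436 with an estimated correlation). Its leading members were Oas2 (-0.30), Bst2 (-0.27) and Ifit3b (-0.51), and 21 fell adjusted over the list alone. Of the 24 interferon-gamma-inducible genes only Cxcl11 passed, with a 5.93-fold rise, also adjusted over the list alone. That list did not pass (adjusted p = 0.292) except without knockout replicate 9 (adjusted p = 0.0456; range over alternatives 0.0456 to 0.974). In the lysosome list 10 of 30 genes fell (median -0.14, adjusted p = 4.39e-10; adjusted p = 0.432 with an estimated correlation), and 19 fell adjusted over the list alone. They were led by the membrane protein gene Cd63 (-0.43), the protease gene Ctsd (-0.50), the proton pump gene Atp6v1a (-0.34) and the protease gene Ctsb (-0.30). In the macrophage identity list 7 of 18 genes fell, led by Vcam1 and Cd63 (median -0.14, adjusted p = 4.51e-06; adjusted p = 0.436 with an estimated correlation). Adjusted over the list alone, the count was also 7. The call of Cd63 was lost with all 16 libraries in 1 fit (adjusted p = 0.077) and in the authors' deposited table (0.0532), in a range of 4.99e-05 to 0.077.

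In the complement list 3 of 18 genes fell and 1 rose. Among those that fell were the receptor gene C5ar2 (-0.49) and the ficolin gene Fcna (-0.74). The list had a median of -0.14 (adjusted p = 0.000917; adjusted p = 0.432 with an estimated correlation), with 1 higher and 7 lower adjusted over the list alone. The lipid list held 2 rises and 4 falls, led by the nuclear receptor gene Nr1h3 (-0.53) and the lipase gene Lpl (0.47). Its median was -0.09 (adjusted p = 0.0208; adjusted p = 0.436 with an estimated correlation), with 3 higher and 8 lower adjusted over the list alone. The lipid list call was lost without wild-type replicate 2 (adjusted p = 0.0559) or knockout replicates 6 (0.05) or 9 (0.0629), in a range of 0.0039 to 0.436. The call of Lpl was lost with all 16 libraries in 1 fit (adjusted p = 0.12) and in the authors' deposited table (0.0537), in a range of 0.00213 to 0.12. Of 26 matrix and angiogenic genes 3 fell, also adjusted over the list alone, led by the protease gene Mmp2, at 0.408 of the wild-type mean, and the inhibitor gene Timp2 (-0.37). That list had a median of -0.11 (adjusted p = 0.0066; adjusted p = 0.436 with an estimated correlation) and did not pass without wild-type replicate 2 (0.0553; range 0.000339 to 0.436). The call of Timp2 was lost with all 16 libraries in 1 fit (adjusted p = 0.239) and in the authors' deposited table (0.195), in a range of 0.00469 to 0.239. Cholesterol synthesis genes had a median of 0.14 (list adjusted p = 2.42e-05; adjusted p = 0.436 with an estimated correlation). None of the 20 passed singly, and 6 rose adjusted over the list alone.

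Markers of other cells moved as well. All 5 measured red blood cell genes fell in macrophages, also adjusted over the list alone, led by Hbb-bt (-1.44) and Hba-a2 (-1.19). That list had a median of -1.19 (adjusted p = 2.24e-06; adjusted p = 0.432 with an estimated correlation). Hemoglobin genes have near-identical copies, and the call of Hba-a2 was lost with quality weights on the recovered reads (adjusted p = 0.0572; range 0.00121 to 0.0572). Fibroblast and sarcoma markers had a median of -0.82 (list adjusted p = 1.17e-05; adjusted p = 0.436 with an estimated correlation). None of these 15 markers passed singly, and 3 fell adjusted over the list alone.

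**Figure D2:**
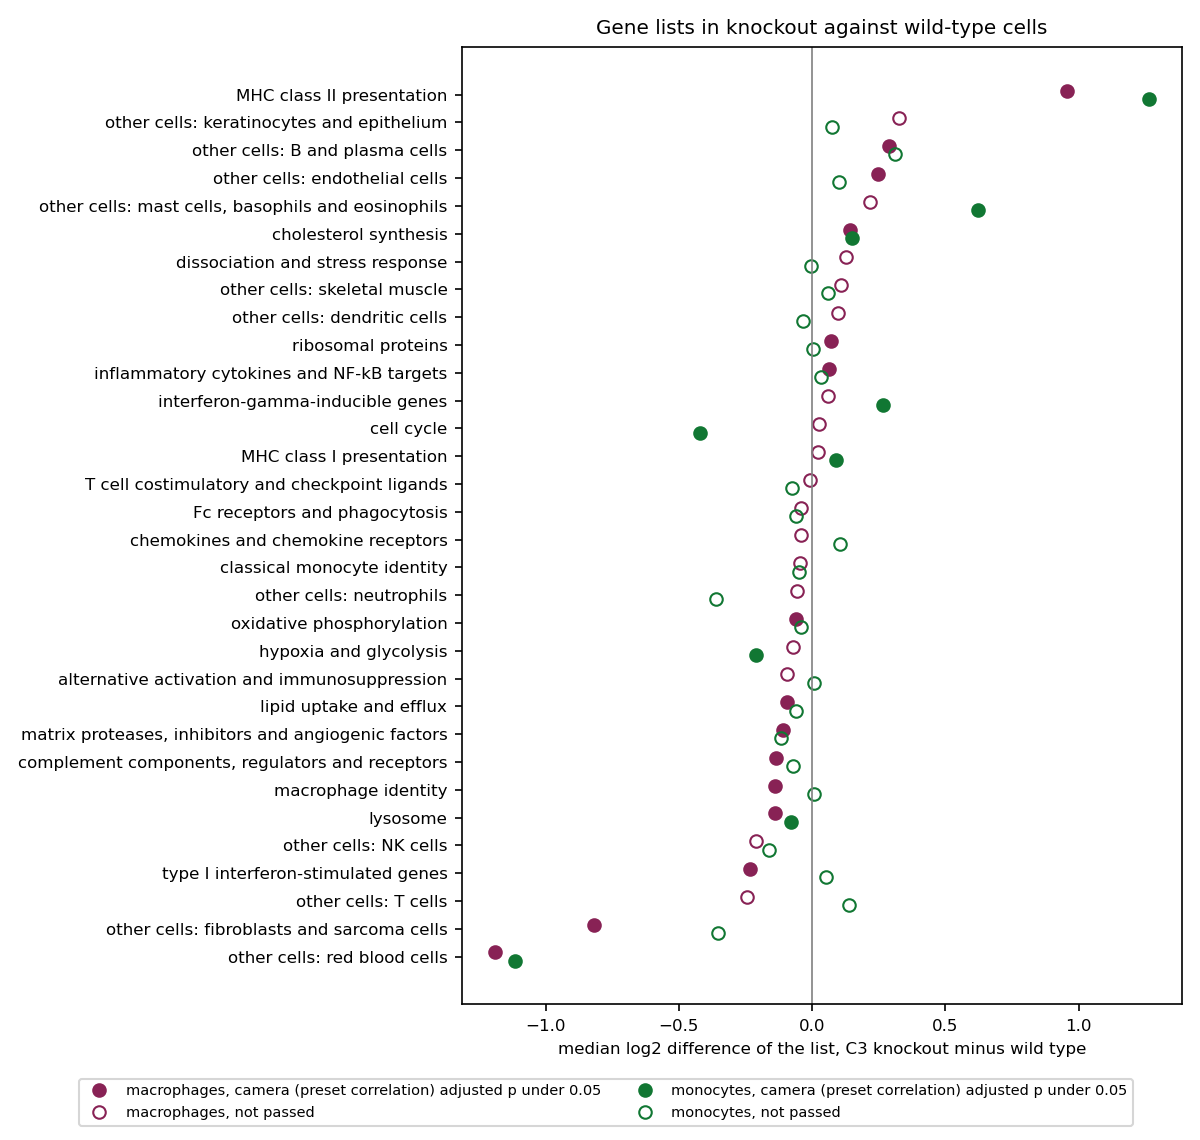
Median log2 difference between knockout and wild-type cells for each gene list with at least 3 measured genes, in macrophages and monocytes; filled points passed camera with the preset correlation. The class II list stood highest in both cell types, at 0.96 and 1.26, and the red blood cell list lowest, at -1.19 and -1.11.

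The second comparison asked the same of monocytes. Here 9 of 13 class II genes rose, 10 adjusted over the list alone, but the list call was lost with an estimated correlation (adjusted p = 0.483). H2-Aa went from 8014 ± 2070 to 68820 ± 15600 normalized reads and Ciita from 603 ± 128 to 5502 ± 1230 (SD, n = 4 per group). The interferon-inducible chemokine gene Cxcl11 rose 7.23-fold. Of 32 genes of hypoxia and glycolysis 5 fell, and of 35 cell cycle genes 3, but both list calls were lost with an estimated correlation (adjusted p = 0.617 for each). In all, 427 of 12867 genes passed (limma, adjusted p under 0.05), 180 higher and 247 lower in the knockout, and 172 of them differed at least 2-fold in reads. With TMM scaling 229 were higher and 207 lower. The values of both genotypes did not overlap in 11.1% of tested genes, against 2.86% by chance. The count was 981 with all 16 libraries in 1 fit and 1329 in the authors' deposited table. It was 282, 263 and 280 without wild-type replicates 2, 3 and 4, and 237 and 243 without knockout replicates 8 and 9.

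The largest monocyte rises were those of Hebp1, Cd209a, Trim34b, Retnlg, Gprc5b, Ciita, Gdpd3, H2-Eb1, Cxcl11 and H2-Aa. Hebp1 rose from 20.6 ± 7.39 to 1751 ± 443 normalized reads (SD, n = 4 per group). Cd209a, a lectin gene of monocyte-derived dendritic cells, rose from 9.12 ± 5.63 to 422 ± 335 normalized reads (SD, n = 4 per group; log2 difference 3.66 ± 0.50 SE, adjusted p = 0.00418), with a wide spread between knockout mice. Its call was lost with voom on the recovered reads (adjusted p = 0.133), and with quality weights (0.101), in a range of 3.33e-08 to 0.133. The largest falls were those of Trim12a, Wfdc21, Trim5, Smarcd1, Eps8, Lrg1, Cd38, Lpin1, Cd22 and Nucb2. Eps8, an actin regulator gene on chromosome 6, fell to 0.192 of the wild-type mean and Cd38, an NAD-consuming surface enzyme gene, to 0.221. The fall of Lrg1 (-1.67, adjusted p = 0.0275) did not pass without wild-type replicates 1, 2 or 4 (adjusted p = 0.054, 0.0508 and 0.0914) or knockout replicates 6, 8 or 9 (0.0646, 0.0597 and 0.0732), in a range of 0.00421 to 0.0914.

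In monocytes 9 of 13 class II presentation genes rose and none fell, led by Ciita, H2-Aa and Cd74 (1.77). The list had a median of 1.26 (camera adjusted p = 3.86e-15, or 0.483 with an estimated correlation), and 10 rose adjusted over the list alone. The class II list also passed fry (adjusted p = 0.00216). Of 13 dendritic cell markers Cd209a rose and Itgax fell, and 5 rose and 1 fell adjusted over the list alone, but that list did not pass (adjusted p = 0.267; adjusted p = 0.784 with an estimated correlation). In the interferon-gamma-inducible list 4 of 24 genes rose, led by Cxcl11 and the transcription factor gene Batf2 (0.78). That list had a median of 0.26 (adjusted p = 1.66e-07; adjusted p = 0.617 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. In the hypoxia and glycolysis list 5 of 32 genes fell, led by the lactate exporter gene Slc16a3 (-0.51) and the oxygen sensor gene Egln3 (-0.96). The list had a median of -0.21 (adjusted p = 4.87e-11; adjusted p = 0.617 with an estimated correlation), and 19 fell adjusted over the list alone. In the cell cycle list 3 of 35 genes fell, led by the mitotic genes Nusap1 (-0.86) and Bub1b (-0.48). That list had a median of -0.42 (adjusted p = 9.38e-11; adjusted p = 0.617 with an estimated correlation), and 16 fell adjusted over the list alone. Of the cholesterol synthesis list 2 of 20 genes rose, Idi1 (0.46) and Cyp51 (0.27), and 9 rose adjusted over the list alone. Its median was 0.15 (adjusted p = 6.60e-07; adjusted p = 0.617 with an estimated correlation). Red blood cell genes had a median of -1.11 (list adjusted p = 0.000201; adjusted p = 0.617 with an estimated correlation). None of these 5 genes passed singly in monocytes, and 4 fell adjusted over the list alone.

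Several of these monocyte calls lay near the threshold and were lost when 1 library was left out. Batf2 did not pass without wild-type replicate 4 (adjusted p = 0.0502) or knockout replicate 9 (0.0584), in a range of 2.88e-06 to 0.0584. Egln3 did not pass without wild-type replicates 2, 3 or 4 (adjusted p = 0.0737, 0.0741 and 0.0645) or knockout replicates 6 or 8 (0.0816 and 0.0578), in a range of 0.00292 to 0.0816. Nusap1 did not pass without knockout replicate 9 (adjusted p = 0.0541; range 7.06e-07 to 0.0541). Bub1b did not pass without wild-type replicate 1 (adjusted p = 0.0545) or knockout replicates 8 or 9 (0.0549 and 0.0606), in a range of 2.53e-05 to 0.0606. Idi1 did not pass without wild-type replicates 2, 3 or 4 (adjusted p = 0.0521, 0.0501 and 0.0515) or knockout replicates 8 or 9 (0.0736 and 0.0697), in a range of 0.000813 to 0.0736. Cyp51 passed in none of the fits without wild-type replicates 1, 2, 3 or 4 (adjusted p = 0.0738, 0.0883, 0.104 and 0.0555) or knockout replicates 6, 8 or 9 (0.0915, 0.122 and 0.118), in a range of 0.0224 to 0.122.

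Of 12383 genes tested in both cell types, 167 were called in both: 83 higher in both, 82 lower in both and 2 in opposite directions. Independent lists of these sizes would share 4.5 higher and 7.6 lower. The libraries of both cell types came from the same 8 mice, so part of the excess may come from shared animals. Called genes also lay close together on the chromosomes. In macrophages 7 windows of 5 Mb held more called genes than expected and in monocytes 10, against at most 2 and 1 in 1000 shuffles. In the window from 5 to 10 Mb of chromosome 17, 13 of 30 tested genes were called in macrophages and 13 of 30 in monocytes. Other windows enriched in both cell types lay on chromosome 6 (135 to 140 Mb) and chromosome 7 (80 to 85, 100 to 110 and 115 to 120 Mb), where Hebp1, Trim12a, Trim5, Trim34b, Sema4b, Plekha7, Eps8, Gprc5b and Nucb2 lie. Without the genes of the 6 shared windows the counts were 610 in macrophages and 332 in monocytes.

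**Figure D3:**
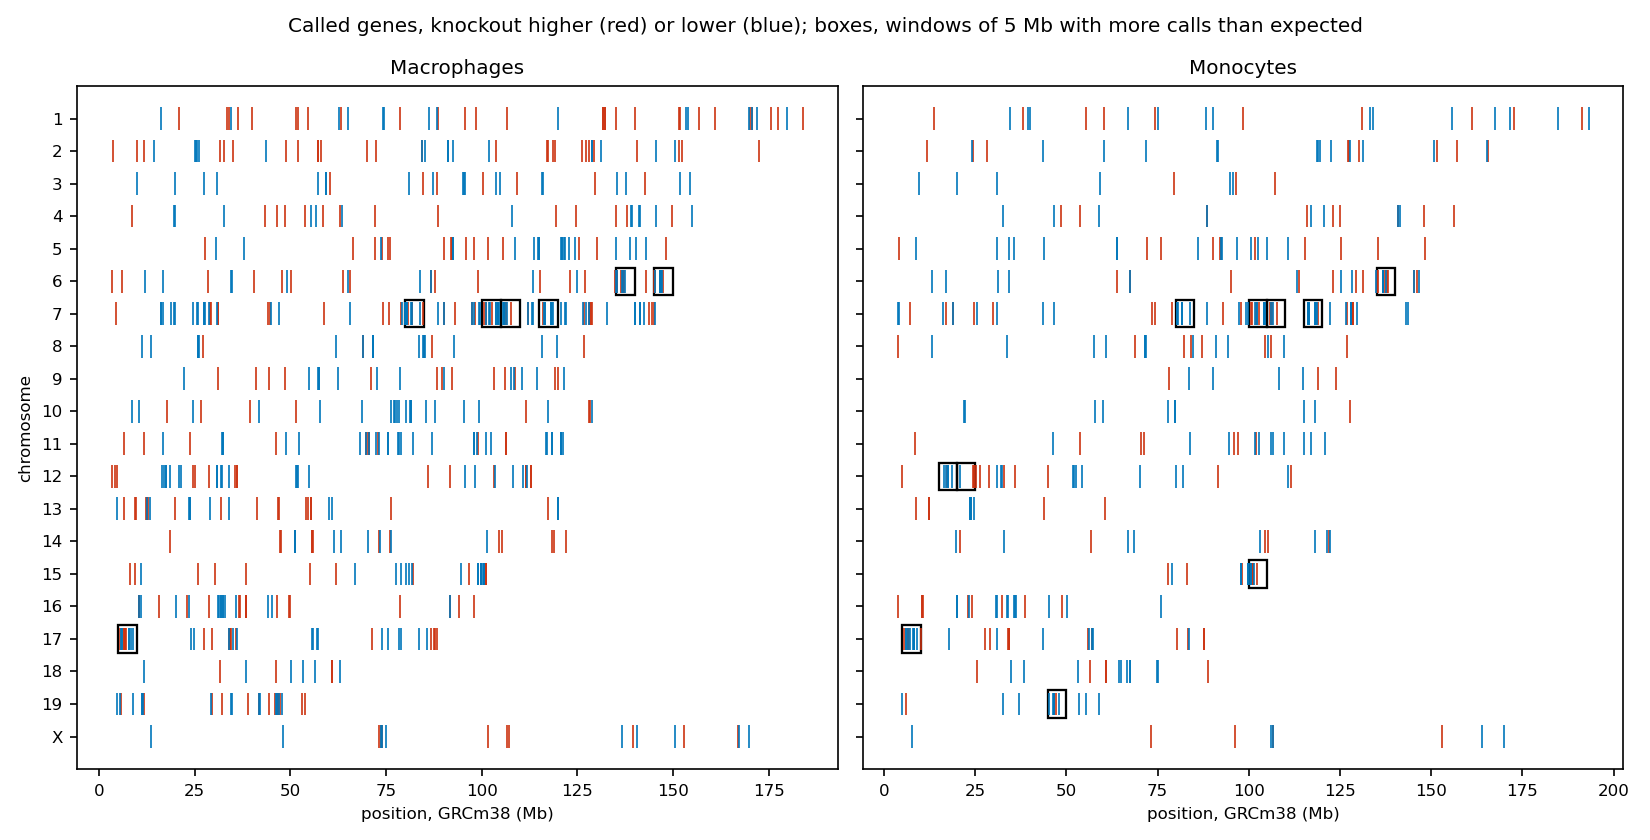
Start positions (GRCm38, Mb) of called genes on each chromosome in macrophages and monocytes, knockout higher in red and lower in blue; boxes are 5 Mb windows with more called genes than expected. There were 7 boxes in macrophages and 10 in monocytes, 6 of them shared.

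The third comparison set macrophages against monocytes of the same wild-type tumours. Of the sort markers, Ly6c2 had 10.3 ± 6.93 normalized reads in macrophages and 16220 ± 2796 in monocytes (SD, n = 4 per group), and Adgre1, which encodes F4/80, was 4.60-fold higher in macrophages. Both gates left out CD11c-positive cells, yet RNA of Itgax, which encodes CD11c, stood at 6202 ± 596 normalized reads in macrophages and 4422 ± 579 in monocytes (SD, n = 4 per group). Macrophages were higher in the complement gene C1qc (12.4-fold) and in Ms4a7 (9.05-fold). Monocytes were higher in Chil3, Plac8 and Hp. C3 itself was lower in macrophages (-1.44 ± 0.09 SE, adjusted p = 5.45e-07). In all, 8094 of 12769 genes passed (limma, adjusted p under 0.05), 4050 higher in macrophages and 4044 lower (4568 and 3519 with TMM scaling), and 57.6% of tested genes did not overlap, against 2.86% by chance.

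By size, the genes highest in wild-type macrophages were Cadm1, Gas6, Cd207, Fcrls, Tlr12, Col14a1, Hpgds, Asb2, Cspg4 and Slco2b1. Gas6, a ligand of the TAM receptors, was 78.0-fold higher and Fcrls, an Fc receptor-like gene, 52.2-fold. Among those lowest in macrophages were Chil3, Ly6c2, Plac8, Hp, Cd177, Lrg1, Lcn2, Plcb1 and S100a8. Chil3, which encodes a chitinase-like protein, had 44450 ± 18260 normalized reads in monocytes and 13.3 ± 11.4 in macrophages (SD, n = 4 per group). All 35 measured cell cycle genes were higher in macrophages, also adjusted over the list alone, led by Mcm5 (1.56) and Mcm2 (1.63), helicase subunits of DNA replication. The list had a median of 1.54 (camera adjusted p = 1.24e-13; adjusted p = 0.516 with an estimated correlation). Of 18 macrophage identity genes 13 were higher and 3 lower, with 14 higher and 3 lower adjusted over the list alone (median 1.54, adjusted p = 6.28e-05; adjusted p = 0.516 with an estimated correlation). All 20 classical monocyte genes were lower, also adjusted over the list alone (median -3.11, adjusted p = 3.64e-14; adjusted p = 0.0625 with an estimated correlation). Of 32 hypoxia and glycolysis genes 30 were lower, also adjusted over the list alone, led by Ddit4 (-2.31) and Ankrd37 (-1.78). That list had a median of -0.79 (adjusted p = 2.33e-11; adjusted p = 0.516 with an estimated correlation). Of 35 type I interferon-stimulated genes 33 were lower, also adjusted over the list alone, led by Sp100 (-0.95) and Isg20 (-1.70). Their median was -0.95 (adjusted p = 5.92e-11; adjusted p = 0.592 with an estimated correlation).

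Markers of other cells differed between the gates in wild-type tumours. Ly6g, which encodes Ly6G, stood at only 1.2 normalized reads in wild-type monocytes, so neutrophils in that gate were not shown. All 9 measured neutrophil markers were lower in macrophages, also adjusted over the list alone (median -3.97, adjusted p = 2.73e-06; adjusted p = 0.347 with an estimated correlation). So were 14 of 17 fibroblast and sarcoma markers (median -1.12, adjusted p = 0.00523; adjusted p = 0.694 with an estimated correlation), with 1 higher and 14 lower adjusted over the list alone. With the mouse as a block, the lists of MHC class I (adjusted p = 0.0399; range over alternatives 0.0329 to 0.814) and T cell ligands (0.0463; range 0.0463 to 0.694) passed in addition. The same block added the lists of T cells (adjusted p = 0.0463; range 0.0347 to 0.694) and red blood cells (0.0043; range 0.0043 to 0.694). Without the block, the MHC class I list passed without monocyte replicates 2 (adjusted p = 0.0489) or 4 (0.0329), and the T cell list without monocyte replicate 2 (0.0443) and with TMM scaling (0.0347). The red blood cell list passed without macrophage replicate 2 (adjusted p = 0.0201) or monocyte replicates 3 (0.0446) or 4 (0.0315), and with TMM scaling (0.0347).

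The fourth comparison repeated this in knockout tumours. Cxcl13 headed the genes higher in macrophages, with 1848 ± 488 normalized reads against 6.33 ± 4.58 in monocytes (SD, n = 4 per group; log2 difference 5.83 ± 0.20 SE, adjusted p = 1.21e-09). It was followed by Cadm1, Cd207, Col14a1, Slco2b1, Asb2, Mb21d2, Hpgds, Chst7 and Tanc2. Ly6c2, Chil3, Cd177, Plac8, Hp, F10, Arhgef37, Plcb1 and Serpinb10 were among the lowest. In all, 7732 of 12772 genes passed (limma, adjusted p under 0.05), 3953 higher in macrophages and 3779 lower, and 55.2% of tested genes did not overlap, against 2.86% by chance. All 35 cell cycle genes were higher, also adjusted over the list alone, led by Mcm3 (1.84) and Bub1b (1.94). Their median was 2.05 (camera adjusted p = 3.53e-19; adjusted p = 0.418 with an estimated correlation). All 20 classical monocyte genes were lower, also adjusted over the list alone (median -2.79, adjusted p = 2.44e-16), which held at adjusted p = 0.0131 with an estimated correlation. Of 13 class II genes 11 were higher, also adjusted over the list alone, led by H2-Ob (1.22), Lgmn (0.82) and H2-Eb1 (2.80-fold). Their median was 0.81 (adjusted p = 0.000646; adjusted p = 0.607 with an estimated correlation). Markers of other cells were also higher in monocytes: all 9 neutrophil markers, also adjusted over the list alone, led by Mmp8 (-4.33) and Padi4 (-3.51), with a median of -3.15 (adjusted p = 4.03e-05; adjusted p = 0.303 with an estimated correlation). The same held for 12 of 15 fibroblast and sarcoma markers (13 adjusted over the list alone), led by Acta2 (-1.66) and Fbn1 (-1.40), with a median of -1.71 (adjusted p = 0.000365, or 0.622 with an estimated correlation). Ly6g stood at only 1.65 normalized reads in knockout monocytes, so neutrophils in that gate were not shown here either. With the mouse as a block, the lists of alternative activation (adjusted p = 0.0243; range over alternatives 0.0243 to 0.622), NK cells (0.0243; range 0.0243 to 0.607) and red blood cells (0.0118; range 0.00691 to 0.622) passed in addition. Without the block, the alternative activation list passed without monocyte replicate 6 (adjusted p = 0.0305), and the NK list without macrophage replicate 8 (0.0487) or monocyte replicates 8 (0.0459) or 9 (0.0334). The red blood cell list passed without macrophage replicate 7 (adjusted p = 0.0472) or monocyte replicates 8 (0.00691) or 9 (0.0422), and with TMM scaling (0.0443).

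The last comparison tested whether the knockout effect differs between the cell types. Cxcl13 led the genes with a more positive effect in macrophages (difference of effects 5.41 ± 0.31 SE, adjusted p = 1.33e-08), followed by Mb21d2, Wfdc21, Il1r2 and Lrg1. Il1r2, a decoy receptor gene for interleukin 1, had a log2 difference of 1.16 in macrophages and -1.07 in monocytes. Cd209a, Ccr3, Gsg1, Sema4b and Gprc5b had the most negative differences of effects. The class II rise was larger in monocytes, where 5 of 13 genes passed, led by H2-Aa (-0.99, adjusted p = 0.00845) and H2-Ab1 (-1.001, adjusted p = 0.0126). That list had a median of -0.21 (camera adjusted p = 4.33e-07; adjusted p = 0.651 with an estimated correlation), with 1 higher and 6 lower adjusted over the list alone. The call of H2-Ab1 was lost without the filter on low values (adjusted p = 0.0679; range 0.00231 to 0.0679).

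In all, the test of the difference called 81 of 13134 genes (limma, adjusted p under 0.05), 47 with a more positive effect in macrophages and 34 with a more negative effect. With TMM scaling these were 29 and 47. With the mouse as a block the count was 251, and it was 48 without wild-type macrophage replicate 3 and 125 without knockout monocyte replicate 7. Wfdc21, Cd209a, Gprc5b and Cxcl13 averaged under 2 normalized reads in at least 1 group, where the scale compresses changes. With voom on the recovered reads, Cxcl13 (adjusted p = 0.132; range over alternatives 6.39e-10 to 0.24), Mb21d2 (0.068; range 1.35e-05 to 0.0863) and Wfdc21 (0.304; range 0.000445 to 0.428) did not pass. Neither did Lrg1 (adjusted p = 0.356; range 0.00885 to 0.356), Cd209a (0.755; range 0.000737 to 0.755) and Gprc5b (0.593; range 0.0102 to 0.6). The call of Lrg1 was lost without macrophage replicates 2, 3, 4, 6, 7, 8 or 9 (adjusted p = 0.0799, 0.092, 0.0773, 0.0776, 0.0807, 0.0557 and 0.0637) or monocyte replicates 2, 4, 8 or 9 (0.0546, 0.0684, 0.0785 and 0.0639). That of Cd209a was lost without macrophage replicates 1, 3, 4, 6 or 7 (adjusted p = 0.0509, 0.0601, 0.0537, 0.053 and 0.058) or monocyte replicates 2 or 4 (0.0546 and 0.0557). That of Gprc5b was lost without macrophage replicates 1, 2, 3, 4, 6, 8 or 9 (adjusted p = 0.08, 0.0916, 0.0885, 0.0754, 0.0679, 0.0703 and 0.0563) or monocyte replicates 2, 3, 4, 6, 7, 8 or 9 (0.084, 0.0607, 0.0725, 0.0587, 0.0622, 0.0638 and 0.0896). With the mouse as a block, the lists of MHC class I (adjusted p = 0.0236; range 0.000724 to 0.793) and of fibroblast and sarcoma markers (0.0104; range 0.000128 to 0.793) also passed. Without the block, the MHC class I list passed without macrophage replicates 4 or 8 (adjusted p = 0.00693 and 0.000724) or monocyte replicates 3, 7 or 9 (0.0185, 0.00248 and 0.0443). The fibroblast and sarcoma list passed without macrophage replicates 3, 4, 6 or 7 (adjusted p = 0.015, 0.0311, 0.0025 and 0.0253) or monocyte replicates 1, 3 or 8 (0.00394, 0.0311 and 0.000128).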

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

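The test of a chromosome segment over the class II genes and the test of dendritic cells without abundant markers were chosen only after the result was seen. The splits of the samples and the other tests of the class II rise were fixed before their results were seen.

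Of 13 class II genes 10 rose in knockout macrophages and 9 in monocytes, with list medians of 0.956 and 1.265, but both list calls were lost with an estimated correlation (adjusted p = 0.432 and 0.483). With fry the list passed in both cell types (adjusted p = 0.000421 in macrophages and 0.00216 in monocytes). A chromosome segment of another strain over the class II region would leave Cd74 and Ciita, on other chromosomes, unmoved, but the smaller of their rises was still 0.87 of the median of the class II genes on chromosome 17, and more macrophages in the monocyte gate were argued against by a median of -0.051 over 410 genes higher in macrophages. More dendritic cells stayed open, although both gates left out CD11c-positive cells: the marker medians of 0.1 in macrophages (95% bootstrap interval -0.118 to 0.26; bound 0.478) and -0.03 in monocytes (-0.11 to 0.62; bound 0.632) included markers so abundant here that they would hide a small share, Bst2 (5503 normalized reads in wild-type and 4252 in knockout macrophages) and Itgax (6202 and 4979; 4422 and 2649 in monocytes), and without the 2, 3 or 4 most abundant markers the intervals reached 0.41, 0.41 and 0.552 in macrophages and 0.695, 0.863 and 1.107 in monocytes, where 5 of 13 markers rose and 1 fell adjusted over the list alone (mean 0.395), Cd209a from 9.12 to 422 normalized reads. More B cells stayed open with medians of 0.29 over 4 markers in macrophages (interval -0.109 to 0.943, past the bound of 0.478) and 0.31 in monocytes (-0.048 to 0.474, under the bound of 0.632 but over only 3 markers); Cd79b stood at 140 and Ighm at 6507 normalized reads in knockout macrophages against 51.5 and 4662 in wild type, and at 133 and 2770 against 102 and 1670 in monocytes, although the CD11b gate should remove most B cells. A wider interferon-gamma response may be part of the pattern, but the list had a median of 0.06 in macrophages (adjusted p = 0.292) and 0.26 in monocytes, so a rise in both cell types was not shown and the hypothesis stays open.

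In each of the 5 comparisons only 1 of 35 splits of the samples, the real one, called as many genes. That is the lowest share that 35 splits can give, so chance was made unlikely but not excluded. Between cell types, splits that mix them widen the spread within groups, so few calls there were fixed in advance. The splits do not part genotype from anything else shared by the mice of a genotype. The real split called 717 genes in macrophages and the highest other split 2. For monocytes the counts were 427 and 1, between cell types 8094 and 2 in wild type and 7732 and 1 in knockout, and for the difference of effects 81 and 0. Among the 8 splits between cell types that part all pairs of a mouse, the highest other called 0 genes in wild type and 0 in knockout by limma.

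A library stood apart from the rest of its group in 10 of 232 group tests, where chance gives 1 in 20, or 11.6. The gap to the nearest library was 0.871 of the group's range for the MHC class I list mean in wild-type macrophage replicate 4 (lowest) and 0.851 for the class II list mean in knockout macrophage replicate 8 (highest). It was 0.891 for Gdpd3 (highest) and 0.954 for Itgax (lowest) in the same knockout macrophage library, and 0.855 for the NK cell list in knockout macrophage replicate 9 (lowest). Among monocytes it was 0.841 for the complement list in wild-type replicate 3 (highest), 0.949 for Cd22 in wild-type replicate 2 (lowest) and 0.849 for Itgax in wild-type replicate 1 (lowest). In knockout monocytes it was 0.842 for the fibroblast and sarcoma list in replicate 8 (lowest) and 0.863 for Trim12a in replicate 7 (highest).

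The knockout effect differed between cell types for 81 genes by the test of the difference. The differences of effects, macrophages minus monocytes, were 5.41 for Cxcl13, 2.705 for Mb21d2, 2.448 for Wfdc21, 2.232 for Il1r2 and 2.174 for Lrg1. They were -3.132 for Cd209a, -1.985 for Ccr3, -1.651 for Gsg1, -1.606 for Sema4b and -1.417 for Gprc5b. The calls of Il1r2, Ccr3, Gsg1 and Sema4b held in every alternative run, and those of the other 6 genes were lost under voom, with the values given beside the comparison.

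Of the lists, 9 differed between cell types with the preset correlation and 0 with an estimated correlation in camera or with fry. The median differences of effects were -0.207 for class II (adjusted p = 4.33e-07; 0.651 with an estimated correlation), -0.262 for type I interferon-stimulated genes (5.05e-16; 0.651) and -0.265 for interferon-gamma-inducible genes (6.88e-05; 0.793). They were 0.482 for the cell cycle (1.6e-15; 0.651), 0.176 for hypoxia and glycolysis (4.33e-07; 0.793) and -0.224 for macrophage identity (6.88e-05; 0.651). Adjusted over the list alone, 6 class II genes had a lower and 1 a higher effect in macrophages, 7 type I interferon-stimulated genes a lower, 11 cell cycle genes a higher and 4 macrophage identity genes a lower effect. In the inflammatory list 3 were higher, and in the alternative activation list 1 was higher and 4 were lower. The other 3 lists lay near the threshold and were lost without any of several libraries. The inflammatory list (0.176, adjusted p = 0.015; range 1.24e-05 to 0.793) did not pass without macrophage replicates 3 or 8 (0.0538 and 0.192) or monocyte replicates 2, 6 or 9 (0.0649, 0.0539 and 0.0749). The alternative activation list (-0.094, adjusted p = 0.0413; range 0.000794 to 0.793) did not pass with TMM scaling (0.105), without macrophage replicates 2, 3 or 9 (0.13, 0.0538 and 0.123) or without monocyte replicates 1, 3, 4, 7 or 8 (0.0938, 0.0886, 0.0551, 0.1 and 0.0525). The lysosome list (-0.053, adjusted p = 0.0271; range 0.00192 to 0.793) did not pass without macrophage replicates 2, 3, 6 or 9 (0.0738, 0.0538, 0.219 and 0.107) or monocyte replicates 1 or 8 (0.201 and 0.0772).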

How the results depend on the processing

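The count models fixed in advance, and scaling within them, were not run. The pseudocount of 1, voom without quality weights, array weights, the fit without genes of enriched windows, protein-coding genes only and the authors' deposited tables were chosen after the data were seen. Over named genes, 13984 results under an alternative kept their side of the threshold, 426 fell short of it, 215 newly passed and 0 reversed. For lists these were 1825, 100, 72 and 0. A reversal was counted only where the result passed in the main fit or in the alternative, so changes of direction among results that passed in neither were not counted. The monocyte count of 427 was 981 with all 16 libraries in 1 fit, which kept 414 of the 427, and 1329 in the authors' deposited table, which shared 417. For both the cause was not tested. In macrophages the 717 calls became 516 with all libraries in 1 fit (473 kept) and 855 in the authors' deposited table (588 shared). With no filter on low values more genes were tested, and the counts were 557 in macrophages, 306 in monocytes and 70 for the difference of effects. The mouse as a block, the paired fit, raised the difference of effects from 81 to 251 calls (78 of the 81 kept; the cause was not tested). It gave 8399 calls between cell types in wild type and 7773 in knockout, and changed no call of a named gene or list there apart from the list calls given with the comparisons. Leaving out 1 library left fewer samples and gave 458 (wild-type replicate 2) to 656 (knockout replicate 6) calls in macrophages and 237 (knockout replicate 8) to 459 (knockout replicate 7) in monocytes. Monocytes also gave 282, 263 and 280 without wild-type replicates 2, 3 and 4 and 243 without knockout replicate 9. Between cell types it gave 7351 to 7782 in wild type and 7051 to 7356 in knockout. The difference of effects gave 48 (wild-type macrophage replicate 3) to 125 (knockout monocyte replicate 7). The other alternatives kept all counts within 1.5 times, at 610 to 772 in macrophages, 332 to 480 in monocytes, 8015 to 8229 in wild type, 7632 to 8292 in knockout and 59 to 115 for the difference. TMM scaling shifted libraries by -0.0388 to 0.0381 on the log2 scale. Of simulated changes of 1.5 fold, 50.7% were found in the test of the difference, so small changes can be missed; recovery was not split by depth or expression level.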

Other observations

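The tests of chromosome positions and of the remaining C3 reads were chosen only after the result was seen.

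Between the cell types of wild-type tumours, 23 of 28 inflammatory genes were lower in macrophages and 2 higher, also adjusted over the list alone, led by the cytokine genes Il1b (-1.63) and Osm (-1.92). The median of these genes was -0.795 (camera adjusted p = 8.51e-06; adjusted p = 0.516 with an estimated correlation). Dissociation and stress response genes moved the same way, with 15 of 29 lower and 5 higher, also adjusted over the list alone (median -0.339, adjusted p = 0.015; adjusted p = 0.694 with an estimated correlation), so an effect of tissue dissociation on the inflammatory genes was not parted from a difference in the tumour. In knockout tumours 13 of these 29 were lower and 1 higher, also adjusted over the list alone (median -0.34, adjusted p = 0.0359; range 0.00502 to 0.702, the highest with an estimated correlation), and the call was lost without macrophage replicate 6 (0.118) or monocyte replicate 8 (0.0741). Of 13 class II genes 11 were higher in macrophages, also adjusted over the list alone, led by Cd74 (1.73) and Lgmn (0.92), with a median of 1.07 (adjusted p = 7.44e-06; adjusted p = 0.516 with an estimated correlation). Complement genes had 12 higher and 3 lower of 18, and 12 and 4 adjusted over the list alone, led by the first-component genes C1qc (2.59) and C1qb (2.16), with a median of 0.302 (adjusted p = 0.015; adjusted p = 0.516 with an estimated correlation). Lysosome genes had 18 higher and 2 lower of 30, and 18 and 3 adjusted over the list alone, among them the glycosidase genes Gusb (0.85) and Hexa (0.75), with a median of 0.288 (adjusted p = 0.000278; adjusted p = 0.592 with an estimated correlation). In knockout tumours 11 of 14 T cell markers were lower in macrophages, led by Cd2 (-1.78) and Lck (-1.53), while Cd4 was higher (1.61), also adjusted over the list alone. Their median was -1.30 (adjusted p = 0.00407; adjusted p = 0.607 with an estimated correlation).

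Smaller lists also moved with the knockout. In macrophages 2 of 5 endothelial markers rose, also adjusted over the list alone, the growth factor receptor gene Kdr (1.15) and Eng (0.64), with a median of 0.247 (adjusted p = 0.0205; adjusted p = 0.432 with an estimated correlation). Of 4 B cell markers Cd79b rose (0.94) and Ighm did not pass (0.37), with 2 higher adjusted over the list alone and a median of 0.287 (adjusted p = 0.0278; adjusted p = 0.436 with an estimated correlation). The B cell list did not pass without wild-type replicate 2 (adjusted p = 0.125; range 0.00133 to 0.436). Oxidative phosphorylation genes had a median of -0.06 (adjusted p = 0.000441; adjusted p = 0.492 with an estimated correlation), and Ndufa4 fell (-0.295), 1 of 32, also adjusted over the list alone, while Cox5a did not pass (-0.14). In monocytes the eosinophil chemokine receptor gene Ccr3 rose (1.47), 1 of 3 mast cell, basophil and eosinophil markers, while Siglecf passed (0.62) only in the count of 2 adjusted over the list alone (median 0.624, adjusted p = 0.00385; adjusted p = 0.617 with an estimated correlation). Epcam, an epithelial adhesion gene chosen after its values were seen, rose in macrophages (log2 difference 1.08, adjusted p = 0.00119; 1.81 to 15.95 normalized reads) and in monocytes (1.43, adjusted p = 0.000938; 2.28 to 27 normalized reads), while the epithelial list did not pass (adjusted p = 0.159 and 0.405).

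Called genes lay close together on the chromosomes. Positions by chance were argued against in monocytes by 62.5% of calls having a called neighbour (at most 57.8% in 1000 shuffles) and by 10 enriched windows against 1, and in macrophages by 7 windows against 2, although the neighbour share of 73.9% was reached by 3 shuffles. A segment around C3 alone was argued against, since at most 16.7% of the calls in enriched windows lay on chromosome 17. The only enriched window on that chromosome, 5 to 10 Mb in both cell types, does not hold C3, so no enriched window lay over the targeted gene. Segments of another strain carried by the knockout line may account for the windows: of 75 calls in the macrophage windows that were tested in both cell types, 92% moved the same way in monocytes, against 78.6% of 630 other calls, with 35.9% of the calls higher. The labels name C57BL/6J for all mice and no breeding history, so this stays a hypothesis that genotypes would have to test, and the 6 shared windows hold 9.3% of macrophage and 14.8% of monocyte calls.

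Reads of C3 remained in knockout libraries, at 30.8% of wild type in macrophages and 32.5% in monocytes. Transcripts still made from the targeted allele may be their source, because the log2 ratio of C3 between monocytes and macrophages differed by only 0.09 between genotypes (1.444 in wild type and 1.353 in knockout). This ratio cannot part such transcripts from RNA of the wild-type sarcoma cells. In knockout libraries it lay -0.35 from that of the fibroblast and sarcoma markers (1.707, interval 1.174 to 1.873). The wild-type C3 ratio of 1.444 lies in that interval too. Against sarcoma RNA, C3 varied less between knockout libraries than these markers, with SD ratios of 0.229 in macrophages and 0.094 in monocytes. Host fibroblasts share the markers, so sarcoma RNA stays open. The CD45 gate should remove both kinds of cell, and the abundant marker Col3a1 stood at 391 normalized reads in knockout macrophages and 2539 in knockout monocytes.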
